A study of Pinus sylvestris with 36 samples.

How the data were processed

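The data are 36 2-colour cDNA microarrays of Pinus sylvestris root RNA. Per the labels, seedlings were inoculated 14 days after germination with homogenised mycelium of 1 of the 3 fungi or with sterile water, and roots were harvested 15 days later. Per the labels' protocols, total RNA was turned into cDNA with a PCR-based synthesis kit (SMART) and labelled with Cy5 or Cy3 by a Klenow reaction. Amplification by PCR can change the relative abundance of transcripts, which limits what a fold measures. The series pairs the 4 RNA samples of a replicate in every combination and with dye swaps. The labels name the replicates A, B and C and do not say that they came from separate plants or inoculations, so p-values here measure the spread between these RNA samples, which may be partly technical.

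The deposited scanner files give, per the file headers, spot intensity and local background intensity for each channel as QuantArray read them from 2 images per slide with 10 micrometre pixels. The values were neither background subtracted nor normalized. Channel 1 was Cy5 and channel 2 was Cy3 per the file headers, and the same dyes stand in the labels. The deposited value table of the series holds a score per spot and array whose scale, centring and direction are not stated. Its column medians ranged from 0.716 to 1.22. Its Spearman correlation with the log ratio of the channels across spots ranged from -0.098 to 0.2 over the 36 arrays, and that with the quotient of mean-centred log intensities from 0.41 to 0.64. Scale, centring and direction therefore stayed unknown, and the score table was not used for any comparison. It was blank in 910 cells, which are exactly the 910 spots that the scanner files mark as set aside, and these spots were given weight 0.

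The files list spot positions and no probe names. The layout was read from the mean log2 intensities of the 6144 spots. Neighbouring blocks of 128 spots carried the same print order (correlation 0.939 to 0.985 in the 24 pairs of blocks, at most 0.476 between other blocks). In the last print line of each block the same probe was repeated further, 4 columns apart (correlation 0.99, at most 0.304 in other lines) and between adjoining block lines (0.987 to 0.999). Averaging all spots of a probe gave 2688 features in 2 spots and 96 features in 8 spots, 2784 in all. The repeated line was recognised only after log2 fold changes of a first fit with 3072 pairs of spots had been seen, because the lowest features of that fit lay in it. All fits and tests were then run again on the 2784 features with their bounds unchanged, except the tests of the scan session and of the slope on the pathogen response, whose bounds were reset after the first fit. The counts under both definitions are given in the closing section. Which spots are controls is not given in the sources used here, so none was left out.

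The fits were run in R 4.3.3 with limma 3.58.1. Background was corrected with normexp (offset 50), log ratios were normalized within each array by global loess, and the spots of a feature were averaged. Within each replicate the 12 arrays were reduced to 1 value per RNA sample by least squares with 4 RNA levels and a dye term, so that repeated hybridisations of an RNA were not counted as replicates. The 12 values were fitted with lmFit and eBayes with treatment and replicate block (6 residual degrees of freedom, 3.22 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg within each of the 6 comparisons and for the F test over treatments. The threshold was an adjusted p under 0.05. All tests were 2-sided. With 3 pairs an exact test by sign flips cannot go below p = 0.25, so single features rest on the spread shared across features in limma.

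Every array joins RNA samples of the same letter, so the block is part of the design. The pairing was also checked on separate-channel log2 intensities (loess, then Aquantile). Samples of the same letter deviated together from their treatment means in all 6 comparisons, with correlations across features of 0.345 to 0.779. Samples of different letters reached 0.489 (Pathogen versus Mycorrhiza), above the lowest value of the same letter, so the block rests on the design and not on these correlations. The intensities given per treatment in the report come from those separate channels. Saturated spots were kept. On the arrays 0.114% to 1.99% of spots were saturated in at least 1 channel, and 2 features were saturated on all arrays in the pathogen channel. Neither of these is named, and 1 of them is among the features called in Pathogen versus Saprotroph. No pair of arrays held identical values (highest correlation of Cy5 log2 intensities 0.9898).

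Of the 18 dye-swap pairs 11 correlated negatively across features, 7 of 9 where pathogen RNA was on the array and 4 of 9 where it was not. The 2 pathogen pairs with a positive correlation were both in replicate C (0.0563 and 0.145). These values follow global loess, and under print-tip loess 15 of the 18 pairs correlated negatively. A dye term was fitted in each replicate.

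The whole fit was tested on simulated arrays with 200 of the 2784 features changed. Recovery in Pathogen versus Control was 12% for changes of 0.25 on the log2 scale, 88% for 0.5, 94% for 0.75 and 100% for 1. With 8 features changed at once, over 25 simulations added after the results had been seen, recovery in Pathogen versus Control was 2% for 0.25, 34% for 0.5, 80% for 0.75 and 100% for 1. With 200 changed, unchanged features made up 2 of the 149 calls there, 9 of 167 in Mycorrhiza versus Control and 9 of 160 in Saprotroph versus Control.

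The samples, comparisons and the rule for named features were chosen before the data were examined, and so were the tests and alternatives other than those that the closing section names as chosen later. The rule took, per comparison with Control, the 10 highest and 10 lowest log2 fold changes among features past the threshold with the same sign in all 3 replicates, 5 and 5 per comparison between fungi, and otherwise the 5 smallest p per direction as not passing. Without a gene table, 2 risen and 2 fallen features are printed with their spot numbers. Gene lists fixed beforehand as patterns on descriptions were not analysed here, because the files used here do not pair features with descriptions. The alternatives covered background correction, normalization, scaling between arrays, set-aside spots, dim features, the median over spots, the block (left out in separate-channel intensities), the unit of replication, direct arrays, an intensity trend, the scan session and leaving out each replicate. The scan session was read from the file headers and numbered 1 to 4.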

Results

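Transcript levels were measured in the roots of Scots pine (Pinus sylvestris) seedlings 15 days after challenge with 1 of 3 fungi or after a mock treatment with sterile water. The fungi stood for 3 ways of living with a root. Heterobasidion annosum is a pathogen that causes root and butt rot of conifers, Laccaria bicolor forms ectomycorrhiza, and Trichoderma aureoviride is a soil saprotroph. The treatments are called Pathogen, Mycorrhiza, Saprotroph and Control below. Each treatment was represented by 3 RNA samples, named replicates A, B and C. Within each replicate the 4 RNA samples were hybridised against each other in all 6 pairs and in both dye orientations on 2-colour cDNA arrays, which gave 12 arrays per replicate and 36 arrays in all. Each RNA sample was therefore read on 6 arrays. Median spot intensity ranged from 2050 to 8750 in the Cy5 channel and from 1444 to 8629 in the Cy3 channel. On every array 100% of the spots exceeded the local background by more than 2 of its standard deviations, a low bar where the background was low (its median in Cy5 ranged from 0 to 161.8). The number of arrays and of RNA samples limits the precision of the values below.

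The arrays carried 2784 features as read from the layout, and the files used here do not pair them with gene names or descriptions. The results are therefore given for the features as a population, with 4 features named by their spot numbers. A feature that rose or fell had a Benjamini-Hochberg adjusted p under 0.05 in limma with the replicate as a block. Fold changes compare RNA samples of the same replicate. They are given on the log2 scale with the standard error (SE) of the fit over n = 3 RNA samples per treatment. The median SE over all features was 0.084. The SE takes the spread as equal in all 4 treatments. Without the pathogen samples its median was 0.065, and sample weights ranged from 0.0855 (Pathogen, replicate C) to 3.74 (Saprotroph, replicate A). The SE may therefore be too small where Pathogen is compared and too large elsewhere.

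The comparison of Pathogen with Control asked how the root transcript population stood 15 days after contact with a root-rot fungus. In pathogen-challenged roots 532 features rose and 491 fell, together 36.7% of the 2784 features tested. Most changes were small. The median log2 fold change was 0.41 among the features that rose and -0.37 among those that fell, and 28 features rose and 19 fell by 2-fold or more. Of the 1023 features called, 974 had the same sign in all 3 replicates. The share of features called increased with signal, from 20.8% in the dimmest to 49.3% in the brightest of 4 groups of 696 features.

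The feature at spots 1320 and 1448 rose most, by 2.44 on the log2 scale (SE 0.21, 5.43-fold, limma adjusted p = 0.000562), and it was higher in 3 of 3 replicates, by 3.04, 2.48 and 1.80. Its log2 intensity was 14.15 ± 0.78 (SD, n = 3) in Pathogen roots against 11.64 ± 0.35 (SD, n = 3) in Control roots, while Mycorrhiza roots stood at 11.84 ± 0.52 and Saprotroph roots at 11.82 ± 0.65. The feature at spots 540 and 668 came next, with a log2 fold change of 2.18 (SE 0.18, 4.53-fold, limma adjusted p = 0.000562) and replicate values of 2.60, 2.46 and 1.47. Against Control its values were near 0 in Mycorrhiza (-0.00073) and Saprotroph (-0.042) roots. The 10 features with the highest log2 fold changes rose by 2.54-fold to 5.43-fold. In the same 10 features the values of Mycorrhiza versus Control lay between -0.15 and 0.27 and those of Saprotroph versus Control between -0.28 and 0.22, none of them past the threshold. Both named features lost their call when only the Pathogen and Control samples entered limma (adjusted p = 0.0541). Their log2 fold changes stayed at 2.44 and 2.18 there with an SE of 0.24, and the residual degrees of freedom fell from 6 to 2.

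The feature printed in 8 spots, the first of them 1402 and 1406, fell most. It was lower by a log2 fold change of -1.59 (SE 0.27, 3.02-fold, limma adjusted p = 0.00299), with replicate values of -2.14, -1.91 and -0.73. Its log2 intensity was 14.72 ± 0.17 (SD, n = 3) in Control roots and 13.21 ± 0.61 (SD, n = 3) in Pathogen roots. A second feature in 8 spots, the first of them 380 and 384, fell with a log2 fold change of -1.51 (SE 0.27, 2.85-fold, limma adjusted p = 0.0037) and replicate values of -2.07, -1.80 and -0.66. Both lost their call without replicate A (-1.32 and -1.23), without replicate B (-1.44 and -1.37), on the direct arrays alone (-1.55 and -1.42) and when only the Pathogen and Control samples entered (-1.59 and -1.51, as in the full fit). The 4 lowest features all belonged to the 96 features that the array carried in 8 spots each. Those at ranks 3 and 4 had replicate values of -1.91, -1.88 and -0.72, and of -1.9, -1.74 and -0.74. The values of the 4 were thus close in every replicate. Whether they are separate transcripts, 1 transcript printed repeatedly or controls is not given in the sources used here. Of these 96 features 8 rose and 34 fell, against 524 that rose and 457 that fell among the 2688 features in 2 spots. The 10 lowest features fell by 2.16-fold to 3.02-fold.

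**Figure D1:**
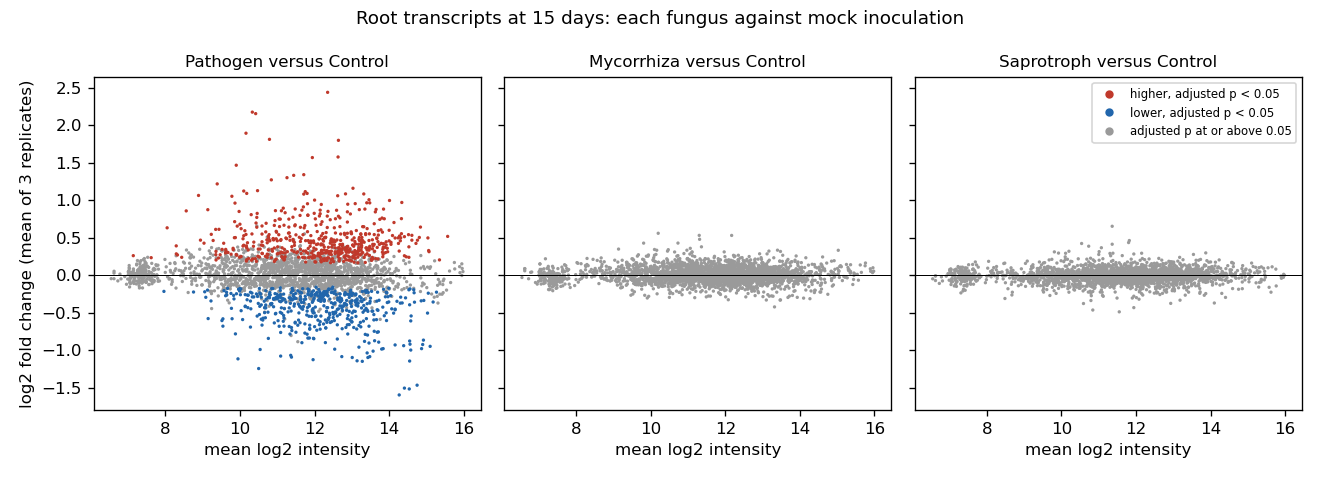
Log2 fold change of each of the 2784 features (vertical axis, mean of 3 replicates) against its mean log2 intensity (horizontal axis) for the 3 fungi against Control. Red and blue points are features above and below Control at an adjusted p under 0.05 in limma, 532 and 491 in the Pathogen panel and 0 in the other panels, and grey points did not pass.

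The pathogen response differed between replicates in pattern and, along the pattern of replicate A, in size. Across features the standard deviation of the Pathogen versus Control log2 fold changes was 0.467 in replicate A, 0.434 in B and 0.343 in C. The log2 fold changes of Pathogen versus Control had a correlation across features of 0.92 between replicates A and B, 0.42 between A and C and 0.24 between B and C (features are not independent replicates). All 18 arrays that carried pathogen RNA showed the response in the labelled direction. The 6 arrays of replicate A were set against the mean response of B and C, with slopes of 1.19 to 1.51. A slope measures only the part of a response that follows the response it is set against. The slope of each pathogen array on the response of replicate A was between 0.745 and 0.975 on the 6 arrays of replicate B and between 0.264 and 0.425 on the 6 arrays of replicate C. The count of called features was 1617 without replicate C, 59 without replicate B and 35 without replicate A. In separate-channel intensities, used in place of log ratios, it was 325 with the replicate block and 134 with no replicate block. It was 70 when only the direct dye-swapped arrays entered and 0 when only the Pathogen and Control samples entered limma (835 at an unadjusted p under 0.05).

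**Figure D2:**
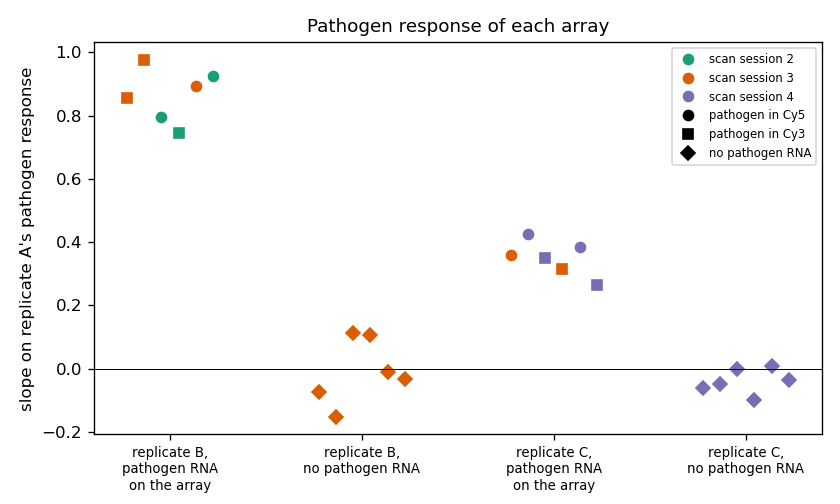
Slope of the log ratios of each array on the pathogen response of replicate A (vertical axis, no unit), signed towards the pathogen where pathogen RNA was on the array, for replicates B and C. Each point is 1 array, coloured by scan session and shaped by the dye of the pathogen RNA. Arrays with pathogen RNA sit between 0.745 and 0.975 in replicate B and between 0.264 and 0.425 in replicate C, and arrays without it between -0.152 and 0.114.

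Images were taken in 4 scan sessions, which overlapped with the replicates. With the scan session as a term in the model 1026 features were called in Pathogen versus Control. The term shifts both dye orientations alike, and most dye-swap pairs fell within 1 session. It could therefore hardly change this count or those of the other comparisons. In replicate A the 6 arrays with pathogen RNA were all scanned in session 1 and the other 6 in sessions 2 and 3. Session and presence of pathogen RNA on an array cannot be told apart there. The direct Pathogen and Control arrays of each replicate fell within 1 session. Of the 1023 features called, 98.4% had the same direction within session 1 (replicate A), 98.9% within session 3 (replicate B) and 91.2% within session 4 (replicate C). These arrays are part of the data from which the features were called.

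**Figure D3:**
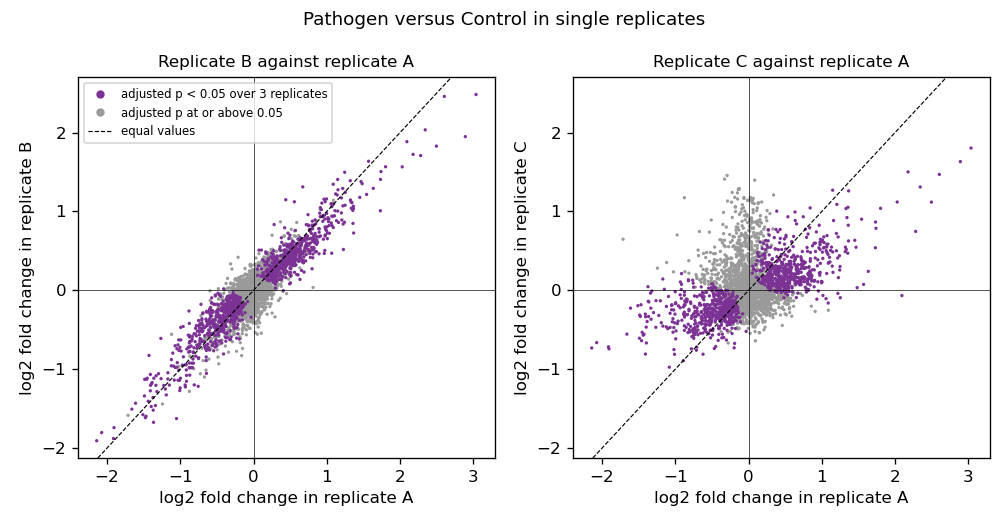
Pathogen versus Control log2 fold change of each feature in replicate B (left, vertical axis) and replicate C (right, vertical axis) against replicate A (horizontal axes). Purple points are the 1023 features with an adjusted p under 0.05 over 3 replicates, grey points the others, and the dashed line marks equal values. The cloud of replicate B follows the line (r = 0.92 across features), and that of replicate C is flatter (r = 0.42) with a group of features near 0 in replicate A that are higher in replicate C.

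The comparison of Mycorrhiza with Control asked the same of roots in contact with a mutualist. No feature passed the threshold in limma, with 0 rises and 0 falls among 2784 features, and 111 features had an unadjusted p under 0.05. The lowest adjusted p was 0.686. Log2 fold changes ranged from -0.42 to 0.56 with a standard deviation across features of 0.10, against 0.35 in Pathogen versus Control. The feature with the smallest p among those above Control had a log2 fold change of 0.53 (SE 0.093, limma adjusted p = 0.686) and was higher in 3 of 3 replicates, by 0.60, 0.53 and 0.47. Simulated arrays took the spread between RNA samples from the fit of all 4 treatments. Array noise was added on top, although that spread already held some of it, so the spread was a cautious upper value. With 200 features changed at once the same fit recovered 94% of features changed by 0.5 on the log2 scale in Mycorrhiza. Of those changed by 0.25 it recovered 24%. With 8 features changed at once it recovered 32% at 0.5, 88% at 0.75 and 0% at 0.25. Under that spread a few changes of 0.5 or less were therefore mostly not detected. The median SE was 0.084 with the pathogen samples in the fit and 0.065 without them, where recovery was not simulated. Mycorrhiza versus Control gave 83 called features when the 36 arrays were counted as independent units, 1 without replicate C, 4 with sample weights and 0 in separate-channel intensities with or without the replicate block.

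Roots in contact with the saprotroph likewise gave no feature past the threshold against Control in limma, 0 higher and 0 lower, with 76 at an unadjusted p under 0.05. The lowest adjusted p was 0.999. Log2 fold changes ranged from -0.485 to 0.656 with a standard deviation across features of 0.088. The highest value was 0.66 (SE 0.13, limma adjusted p = 0.999), with replicate values of 0.85, 0.70 and 0.42. That feature stood at 11.71 ± 0.77 (SD, n = 3) in Saprotroph roots and 11.16 ± 0.56 (SD, n = 3) in Control roots, in log2 intensity. In the simulated arrays 88% of features changed by 0.5 in Saprotroph and 22% of those changed by 0.25 were recovered with 200 features changed at once, and 38% and 0% with 8 changed at once. Without replicate C the count of called features in Saprotroph versus Control was 30, with sample weights it was 79, and with the 36 arrays as independent units it was 46.

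The fungi were also compared with each other on the same arrays. Pathogen roots differed from Mycorrhiza roots in 830 features, of which 433 were higher and 397 lower in Pathogen roots. The feature at spots 1320 and 1448 was higher by 2.17 on the log2 scale (SE 0.21, limma adjusted p = 0.000774) and that at spots 540 and 668 by 2.18 (SE 0.18, limma adjusted p = 0.000744). The 8-spot features beginning at spots 1402 and 380 were lower, with log2 fold changes of -1.28 (SE 0.27) and -1.29 (SE 0.27). None of these 4 calls held without replicate A, where the values were 2.02, 2.01, -0.972 and -0.997, or without replicate B, where they were 2.28, 2.09, -1.08 and -1.09. The count was 1480 without replicate C, 0 without replicate B (644 at an unadjusted p under 0.05) and 1 without replicate A. In separate-channel intensities it was 269 with the replicate block and 93 with no replicate block. The direct arrays alone gave 426, and 614 were called when only the Pathogen and Mycorrhiza samples entered. With the scan session as a term 841 features were called, and 799 of the 830 features had the same direction on the direct arrays of replicate C, all of them in session 3. In session 1 (replicate A) 825 of the 827 features measured there had it, and in session 2 (replicate B) 828 of 830. Here too the direct arrays are part of the data from which the features were called.

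Pathogen roots differed from Saprotroph roots in 1105 features, 565 higher and 540 lower in Pathogen roots. The features at spots 1320 and 1448 and at spots 540 and 668 were both higher by 2.22 (SE 0.21 and 0.18). The 8-spot features beginning at spots 1402 and 380 had log2 fold changes of -1.54 (SE 0.27) and -1.53 (SE 0.27), and lost their call without replicate A (-1.28 and -1.25), without replicate B (-1.4 and -1.39) and when only the Pathogen and Saprotroph samples entered (-1.54 and -1.53, as in the full fit). The count was 1552 without replicate C, 64 without replicate B and 76 without replicate A. In separate-channel intensities it was 398 with the replicate block and 165 with no replicate block. It was 195 from the direct arrays and 178 when only the Pathogen and Saprotroph samples entered. With the scan session as a term it was 1096. On the direct arrays 99.9% of these features had the same direction within session 1 (replicate A) and 96.8% within session 4 (replicate C). The direct arrays of replicate B were split between sessions 2 and 3. Again the features had been called from data that include these arrays.

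The 3 comparisons of Pathogen roots all use the same pathogen samples, so their lists of features are not independent. Of the 532 features that rose against Control, 394 also rose against Mycorrhiza and 479 against Saprotroph. Of the 491 that fell against Control, 342 fell against Mycorrhiza and 441 against Saprotroph. Independent lists of these lengths would share 82.7 and 108 risen and 70 and 95.2 fallen features, and simulated unchanged groups on shared pathogen samples shared 0, as they gave no calls in both. Neither value allows for real effects in the shared samples, so how much of the overlap comes from sharing them is open. In all, 715 features were called in each of the 3 comparisons of Pathogen roots, 379 higher and 336 lower. That number was 1258 without replicate C, 1 without replicate A and 0 without replicate B. Among them 19 were 2-fold or more higher and 10 were 2-fold or more lower against each of the other treatments.

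Mycorrhiza and Saprotroph roots did not differ from each other in any feature in limma, 0 higher and 0 lower, with 127 at an unadjusted p under 0.05 and a lowest adjusted p of 0.906. The 36 arrays taken as independent units gave 92. Over all 4 treatments 851 features differed by limma's F test. That count was 1541 without replicate C, 0 without replicate A (436 at an unadjusted p under 0.05) and 0 without replicate B (545). In separate-channel intensities it was 258 with the replicate block and 77 with no replicate block.

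The 3 comparisons with Control share the same control samples. No feature was called in more than 1 of them, 0 in either direction, since neither Mycorrhiza nor Saprotroph gave a call. The log2 fold changes of Pathogen and Mycorrhiza over Control had a covariance across features of 0.0141, against 0.00582 in simulations of unchanged groups on shared controls (range 0.00499 to 0.00679 over 100 simulations). Their correlation was 0.39 against 0.50 in the simulations, and by replicate it was 0.32 in A, 0.52 in B and 0.74 in C. For Pathogen and Saprotroph the covariance was -0.00179 against 0.00587 simulated, and the correlation -0.058 against 0.503. For Mycorrhiza and Saprotroph the covariance was 0.00262 against 0.00587 simulated, or 0.003 when the spread was taken from a fit without the pathogen samples. Replicate C decided how the values for Saprotroph stood to the simulated ones. Without it the covariance was 0.00571 for Pathogen and Saprotroph (r = 0.112) and 0.0079 for Mycorrhiza and Saprotroph (r = 0.622), both above the 0.00252 simulated for 2 replicates. Without replicate A they were -0.00435 and 0.000956 against 0.0112 simulated, and without replicate B -0.000986 and 0.00321 against 0.00985. With the spread taken without the pathogen samples, the simulated values for Mycorrhiza and Saprotroph were 0.0058 without A, 0.00452 without B and 0.00203 without C. For Pathogen and Mycorrhiza the covariance was 0.0169 without A, 0.0204 without B and 0.0216 without C, above the simulated value each time. The simulated values contain no real effects. The 3 control samples are too few to be split into groups of 2, so part of the excess for Pathogen and Mycorrhiza may come from the shared controls. A deviating control sample adds equally to the covariance of every pair, so it cannot account for differences between pairs. In replicate C the covariance was 0.059 for Pathogen and Mycorrhiza, -0.00064 for Pathogen and Saprotroph and 0.00349 for Mycorrhiza and Saprotroph. In the same order it was 0.0198, 0.012 and 0.0127 in A, and 0.0301, 0.00628 and 0.00848 in B.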

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

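The tests on neighbouring blocks, print-tip loess, the scan session and the dye term were chosen after the results they bear on were seen. The same holds for the test on dilution of the pathogen RNA of replicate C, which takes the smaller response of C as given. The others in this part were chosen before.

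The response to the pathogen and the response to the other fungi over the same controls differed, by direct tests of the difference. Pathogen against Mycorrhiza gave 830 called features and Pathogen against Saprotroph 1105.

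The first pattern is the breadth of that difference. A local mark smaller than a print block is argued against by the neighbouring blocks, whose Pathogen versus Control log2 fold changes, fitted separately, correlated at 0.95 across features, and a wider place effect by print-tip loess, which centres each block and under which 90.2% of the 1023 features were called in the same direction. A product of the loess curve is argued against by median centring, under which 90.6% of the 1023 features were called in the same direction. The biological explanation named by the design, a response of the roots to the pathogen, stays a hypothesis. Fungal RNA in the roots, loss of living root cells and differences from PCR amplification may contribute and were not tested.

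Other splits of the samples bear on the same counts. For each comparison the 6 RNA samples make 10 splits, too few for a share under 0.05. In Pathogen versus Control the real split gave 1023 features and the highest other split 11, and 1 of 10 splits reached the real count. In Pathogen versus Mycorrhiza (830) and Pathogen versus Saprotroph (1105) the highest other split gave 0, and again 1 of 10 splits reached the real count. In the 3 comparisons with 0 calls all 10 splits reached the real count of 0. The split with 11 features in Pathogen versus Control was among the 4 splits that part all 3 pairs, and the splits that part fewer pairs gave 0. For the F test 1 of 100 relabellings within replicates, the real one, reached 851 features. The highest other relabelling gave 790, and it was among the 5 that kept the pathogen samples of all 3 replicates together. Without those the highest was 1, so the F test reflects the pathogen samples. Those 5 and the real one are more than 5% of the 100 relabellings. Pathogen samples that stood together by chance are therefore not excluded at the 5% level.

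The second pattern is the smaller response of replicate C along the pattern of replicate A. The log2 fold changes of C correlated with those of A and B at only 0.42 and 0.24 across features. The cause of that difference in pattern was not tested. For the smaller slope, the scan session is argued against by the arrays of replicates B and C that shared session 3. There the mean slope on replicate A's response was 0.338 for the 2 arrays of C. The slopes of the 3 arrays of B ranged from 0.857 to 0.975. The 2 arrays of C set Pathogen against Mycorrhiza and those 3 arrays of B did not, and the Pathogen and Mycorrhiza arrays of B, scanned in session 2, had slopes of 0.745 and 0.797, so no like pair of arrays shared a session. Compression of all log ratios is argued against by the dye term, whose standard deviation across features in C was 1.99 times the mean of A and B, unless the dye bias of C had been larger still before compression. Dilution of the pathogen RNA of C with RNA like that of the control would shrink falls more than rises, with a ratio of ratios near 1.34, and the value was 0.897 (95% bootstrap interval over features 0.751 to 1.13, too narrow to the extent that features are not independent). A weaker or later infection of replicate C may remain as an explanation, and nothing in the labels tests it.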

How the results depend on the processing

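The settings that count each spot, use only the compared treatments, leave out the pathogen samples, weight the samples, keep the block in separate channels or treat the repeated print line as separate features were chosen after seeing the data, and the others before.

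Background correction, loess or median centring, print-tip loess, scaling between arrays, set-aside spots, dim features, the median over spots, an intensity trend and the scan session left every count of called features within 1.5 times its reported value. For Pathogen versus Control these gave 784 (scaling between arrays) to 1081 (print-tip loess). Taking the repeated print line as separate features gave 1146, 951 and 1240 for Pathogen versus Control, Mycorrhiza and Saprotroph, and 974 for the F test. In all, 104 of 148 recomputed counts stayed within 1.5 times, where a 0 that stayed 0 is included. Most of the 104 were such zeros from the comparisons without calls, so the total overstates how stable the pathogen counts were. Of 225 recomputed log2 fold changes of the 4 named features 201 stayed past the threshold, 24 did not, and 0 changed sign.

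The fit with no replicate block used separate-channel intensities, which changes 2 choices at once. Its counts were 134 for Pathogen versus Control, 93 for Pathogen versus Mycorrhiza, 165 for Pathogen versus Saprotroph and 77 for the F test, and 132 of the 1023 features kept their call. Separate channels with the replicate block gave 325, 269, 398 and 258, so changing the values alone lowered the counts and leaving out the block lowered them further. No other call count changed in either. With the 36 arrays as independent units the counts were 1583, 1407 and 1685, with 83 for Mycorrhiza versus Control, 46 for Saprotroph versus Control, 92 for Mycorrhiza versus Saprotroph, 1651 for the F test and 74 features shared between control comparisons, and by construction this treats repeated hybridisations as replicates. Direct arrays only gave 70, 426 and 195. Each spot on its own, over 6144 spots, gave 2206, 1813, 2337 and 1793 (F test). Fits with only the 2 treatments compared gave 0 in Pathogen versus Control (835 at an unadjusted p under 0.05 in limma), 614 in Pathogen versus Mycorrhiza and 178 in Pathogen versus Saprotroph, with fewer samples behind the spread. Sample weights gave 1535 in Pathogen versus Control, 1425 in Pathogen versus Mycorrhiza, 1552 for the F test, 4 in Mycorrhiza versus Control, 79 in Saprotroph versus Control and 30 shared between control comparisons. The weight of the pathogen sample of replicate C was then 0.0855. Without the pathogen samples Mycorrhiza versus Control gave 1.

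Leaving out each replicate gave 35 to 1617 in Pathogen versus Control, 0 to 1480 in Pathogen versus Mycorrhiza, 64 to 1552 in Pathogen versus Saprotroph and 0 to 1541 for the F test. It gave 0 to 1 in Mycorrhiza versus Control, 0 to 30 in Saprotroph versus Control, 0 to 1 in Mycorrhiza versus Saprotroph and 0 to 11 shared between control comparisons. The highest value in each came without replicate C. Apart from the constructions named, the cause of these differences was not tested. The deposited score table was not run as an alternative, because its scale and direction stayed unknown, and the gene list alternatives were not run. Signal over background was at its ceiling on every array, with a median Cy5 background of 0 on some, so it ranks neither arrays nor features. The log2 fold change at spots 540 and 668 was 1.78 with no background correction against 2.18 with it, and fewer dim than bright features were called (20.8% against 49.3%).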

Other observations

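The set of features that moved in replicate C alone, the fit without the pathogen samples, the feature singled out in Mycorrhiza and the slope on the pathogen response were chosen for testing after the results had been seen.

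In Pathogen versus Control 104 features were higher by over 0.5 on the log2 scale in replicate C and within 0.25 of 0 in replicates A and B, against 6 that were lower. The same rule gave 4 higher and 2 lower features for replicate A and 1 higher and 3 lower for replicate B. The Pathogen versus Control values of the 104 features are fixed by that rule. Mycorrhiza versus Saprotroph compares neither sample type of the rule, although its values come from a fit that also holds arrays with Pathogen and Control RNA. There the median log2 fold change of the 104 features was 0.55 in replicate C, with 103 of them above 0. It was 0.0435 in replicate A and -0.0194 in replicate B. Against Control, which the rule does use, the medians in replicate C were 0.439 for Mycorrhiza and -0.0836 for Saprotroph. Over all features the median in replicate C was 0.00739 with a standard deviation of 0.25. Within each block 44 of the 104 lay in print line 5, which held 384 of the 2784 features (Fisher's exact test, 2-sided, p = 2.81e-13, with features taken as independent and the line chosen after its count was seen). Of the 104 features 5 were called in Pathogen versus Control. No explanation was tested.

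A feature was singled out in Mycorrhiza roots after its values were seen. It had a log2 fold change over Control of 0.56 and was higher in 3 of 3 replicates, by 0.56, 0.51 and 0.62. Its limma adjusted p was 0.851 with all 4 treatments (SE 0.13) and 0.017 when the pathogen samples were left out (SE 0.056). It was also the feature called without replicate C. Its value in Pathogen versus Control was -0.078 and in Saprotroph versus Control 0.32.

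The third pattern is the lack of calls for Mycorrhiza and Saprotroph against Control. Spread inflated by the pathogen samples in the shared fit was tested by leaving their values out. The arrays with pathogen RNA still entered the step that gave 1 value per RNA sample, so their noise was not removed. The median SE fell from 0.084 to 0.065, and the comparison with more calls, Mycorrhiza versus Control, then gave 1 called feature, which argues against that spread as the whole cause. Features at an unadjusted p under 0.05 in limma rose from 111 to 265 in Mycorrhiza versus Control. In Saprotroph versus Control they rose from 76 to 152, so that spread may still be part of the cause. Among 2784 unchanged features a share of 0.05 would reach such a p by chance. The counts with the pathogen samples lay below that share. Without them the count for Saprotroph lay near it and that for Mycorrhiza above it. In Mycorrhiza roots a weak response along the pathogen's pattern could not be told apart from none, because the slopes of the 3 replicates on the pathogen response of the other replicates were 0.081, 0.096 and -0.0508 (mean 0.042, SE 0.0466). In Saprotroph roots the slopes were -0.0024, -0.082 and -0.036 (mean -0.0402, SE 0.0232), which argues against such a response with a slope of 0.1 or more and leaves smaller ones open.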
